A study of Mus musculus with 12 samples.

How the data were processed

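Total RNA from GL261 glioblastoma masses was measured on 12 Affymetrix whole-transcript mouse gene arrays. GL261 is a mouse glioma cell line that grows in immunocompetent C57BL/6 mice. Per the labels, GL261 cells were implanted in the brains of male mice aged 8 weeks and the tumours were taken on day 16. The labels give 3 arrays to each of 4 groups: Control, temozolomide (TMZ, 30 mg/kg into the peritoneum), an antibody against PD-1 (Anti-PD-1, 10 mg/kg into a vein, 2 injections per week) and both agents (Combination). They state neither the dosing days nor what the Control animals received.

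The authors processed the arrays with RMA in the Affymetrix Expression Console; the labels state no version. RMA corrects the background, quantile normalises the arrays together and summarises the probes of each probe set. The deposited values are log2 RMA signals for 41345 probe sets on 12 arrays, ranging from 1.24 to 13.14 with 0 missing values. Array medians lay between 5.06 and 5.12. Arrays give no read depth, and their number, 3 per group, limits the precision.

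The array's annotation named exactly 1 gene symbol for 23521 probe sets, several symbols for 1814 and did not list 16010. Of the single-symbol probe sets, 23328 were matched by gene number to a mouse annotation, which changed 0 symbols. Where a gene had several probe sets (1082 genes), the probe set with the highest mean over all arrays was used. This left 22180 genes, with no filter on brightness. Probe sets with several symbols or no listing entered only an alternative.

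Each gene was fitted with limma 3.58.1 in R 4.3.3 (lmFit with a mean per group, contrasts, eBayes with default settings). All 12 arrays entered the fit, which left 8 residual degrees of freedom. The contrasts were each treatment against Control, Combination against each single agent, TMZ against Anti-PD-1, and the interaction, which is the Combination minus TMZ difference less the Anti-PD-1 minus Control difference. A moderated F test covered the differences among the 4 groups. P values were two-sided and Benjamini-Hochberg adjusted over all genes of a contrast, with a threshold of 0.05. Errors given with log2 differences are standard errors (SE), from limma for single genes and from the scores for lists. Those given with group means are standard deviations (SD). The p values of single genes measure the spread between arrays. The labels do not state that each array came from a separate animal.

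The question of each comparison, the tests, the gene lists, the naming rule and the alternatives were chosen before the data were examined, except where stated. The 34 lists held 710 entries, of which 629 were measured (609 distinct genes, 6 to 29 per list). Immune cell lists covered T cells, cytotoxic lymphocytes, checkpoint and costimulatory receptors, regulatory T cells, natural killer cells, B cells, plasma cells, microglia, monocytes and blood-derived macrophages, alternatively activated macrophages, neutrophils and dendritic cells. Response lists covered MHC class I and class II presentation, the interferon gamma response, the type I interferon response, inflammatory cytokines and NF-kB targets, complement and scavenger genes, immediate early genes, p53 targets, DNA repair, DNA replication and G1/S, mitosis, apoptosis, hypoxia and cholesterol biosynthesis. Tissue lists covered neurons, oligodendrocytes, astrocytes, choroid plexus and ependyma, endothelium, fibroblasts with pericytes and matrix, glioma and neural progenitors, and blood cells with haemoglobin. The lists were written from general knowledge of the tissue.

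Lists were tested with limma's camera at its preset inter-gene correlation of 0.01, adjusted over the 34 lists. Camera compares the genes of a list with all other genes. At the preset correlation its p values therefore do not measure the spread of a list between arrays. Each list was tested again with a correlation estimated from the arrays, and with fry. Fry asks whether a list's genes move on balance in 1 direction without comparing them with other genes. A list score is the mean over its genes of the log2 value minus the gene's mean over all arrays. Scores were compared by exact permutation tests, two-sided; 3 arrays against 3 give 10 splits and an exact p of at least 0.1. Members passing are given over all genes tested and adjusted over the list alone.

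Named genes were, per contrast, the 10 largest rises and 10 largest falls among genes past the threshold whose groups did not overlap. Where fewer than 5 passed in a direction, the 5 with the smallest unadjusted p among genes whose groups did not overlap were taken. Those of them that missed the threshold are said to have missed it. The interaction carried no condition on overlap. To these were added the 4 members with the smallest p of each list past its threshold, and in comparisons with Control always Pdcd1, Cd274, Cd8a, Ifng, Gzmb, Foxp3, Cdkn1a, Mgmt, Mki67 and P2ry12. Predicted genes, olfactory receptors, immunoglobulin and T cell receptor segments, microRNAs and small nucleolar RNAs were counted instead of named in the first part of the rule.

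Alternatives were: fitting only the groups compared, an intensity trend or robust variances in eBayes, array weights, a repeated quantile normalisation, centring each array on its median, leaving out genes with a mean below 5.72 (the median gene), averaging the probe sets of a gene, testing all probe sets, adding a 1.5-fold threshold, the replicate number as a block, a covariate for brain tissue (the mean of the neuron and oligodendrocyte scores), and leaving out each array in turn. Added after the data were seen were a fit without Control replicate 3 and TMZ replicate 2, which lay apart from their groups in a principal component analysis, a covariate from the neuron scores alone, and a comparison of the 9 treated arrays with the 3 Control arrays. The correlation of treatment effects that share the Control arrays, and the overlap of their called genes, were compared with 100 simulations without any effect and the correlation also with estimates from different Control arrays. Splits of the arrays, the real one included, were fitted in the same way: all 10 where there were 10, and otherwise 100, the others drawn at random. Python 3.11.15 with matplotlib 3.10.9 drew the figures.

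The procedure was tested on simulated data with the spread and group sizes of these arrays and genes drawn independently of each other, where some of the 22180 genes were given a change. It recovered 44 of 67 genes changed 1.5-fold (65.7%), 63 of 67 changed 2-fold (94.0%) and 66 of 66 changed 4-fold. Of 182 genes called, 9 had been given no change, and 0 had the wrong sign. A list shifted by 0.5 log2 was recovered, with 0 other lists called. Because the genes were drawn independently, this cannot show how often correlated genes give false list calls. In the real arrays the estimated correlation within the mitosis list was 0.52.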

Results

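The data consist of gene expression values of 12 arrays from GL261 tumours, 3 each from the Control, TMZ, Anti-PD-1 and Combination groups. TMZ is an alkylating agent, and the antibody blocks the inhibitory receptor PD-1 of T cells. The series was made to compare tumour expression after either agent alone and after both. Pairwise correlations between arrays over all probe sets lay between 0.984 and 0.991. The first 3 principal components of the 22180 genes held 26.6%, 11.1% and 9.81% of the variance. Control replicates 1 and 2 lay at -20.1 and -26.4 on the first component, whereas Control replicate 3 (-1.28) lay among the treated arrays, which ranged from -4.10 to 13.9. TMZ replicate 2 stood apart on the third component, at 20.9. The mean log2 level over all arrays was 9.87 for neuron, 8.69 for astrocyte and 8.58 for oligodendrocyte markers, against 4.87 for the mitosis genes. The labels do not state how much brain tissue each sample held. Mean levels of natural killer cell (3.84), cytotoxic lymphocyte (4.50) and T cell markers (4.76) lay below the median gene at 5.72. The medians of Control replicate 3 (5.118) and TMZ replicate 2 (5.118) lay near the upper end of the range over all arrays, 5.062 to 5.120. Control replicates 1 and 2 had medians of 5.086 and 5.092. Whether this small difference goes with the place of the arrays was not tested.

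TMZ was compared with Control to see how the alkylating agent alone altered the tumours, and cell cycle genes were lower after it. The mitosis and DNA replication lists passed in camera at its preset correlation but not with an estimated correlation (camera adjusted p = 0.0894 for both). Of the named genes, Moxd1 (probe set 17232215), which encodes a monooxygenase related to dopamine beta-hydroxylase, fell most. It averaged 8.78 ± 0.73 log2 (SD, n = 3) in Control and 6.01 ± 0.43 in TMZ, a 6.80-fold lower signal (log2 difference -2.77 ± 0.34 SE, adjusted p = 0.0277). Ccna2, the cyclin A gene (probe set 17404821), fell 2.28-fold from 6.24 ± 0.43 to 5.05 ± 0.19 (adjusted p = 0.0402). Ect2, needed for cytokinesis, Hmmr, which binds the mitotic spindle, and Dtl, which acts in replication control, fell with log2 differences of -1.25 ± 0.19, -0.76 ± 0.11 and -0.999 ± 0.14. Ccnd1, the cyclin D gene of the G1 phase, fell by 0.80 on the log2 scale (SE 0.13, adjusted p = 0.0476). The remaining named falls were AI662270 (-1.29), Depdc7 (-0.92), the carbonic anhydrase Car6 (-0.92) and the matricellular gene Ccn1 (-0.73). Atp13a5 (probe set 17329533), which encodes a P-type ATPase, rose from 6.22 ± 0.07 to 6.72 ± 0.06, and Inca1, an inhibitor of cyclin-dependent kinases, rose by 0.61 ± 0.09 log2. The sodium channel gene Scn9a, Rccd1 and Npr2 were 0.46, 0.34 and 0.32 higher and missed the threshold (adjusted p from 0.0566 to 0.107). In all these named genes the 3 TMZ arrays lay on 1 side of the 3 Control arrays, which the naming rule required.

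Of 22180 genes, limma called 22 between TMZ and Control, 4 higher and 18 lower, 5 of them of the classes not named; 2496 genes had an unadjusted p under 0.05. The count depended on single arrays. It was 363 without Control replicate 3 and 0 to 7 without any other array, with 0 lacking Control replicate 2 or TMZ replicate 2, 1 lacking Control replicate 1, 2 lacking TMZ replicate 3 and 4 lacking TMZ replicate 1. It also depended on the settings: it was 113 with a variance trend, 1 when all probe sets were tested, 1 with the brain covariate and 0 when only the groups compared were fitted. With the neuron score as a covariate, chosen after the data were seen, it was 0. Moxd1 passed in 5 of 12 fits that left out 1 array, with log2 differences from -3.16 to -2.44.

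As a list, the mitosis genes fell after TMZ: all 29 measured members were lower, with a mean log2 difference of -0.77 (camera adjusted p = 1.16e-38; adjusted p = 0.0894 with an estimated correlation and 0.0099 by fry). Over all genes 3 members passed, Ccna2, Hmmr and Ect2, and 28 passed adjusted over the list alone. Mitosis scores averaged 0.57 ± 0.32 (SD, n = 3) in Control and -0.20 ± 0.12 in TMZ, and the lowest Control score, 0.20 in replicate 3, lay above the highest TMZ score of -0.07. Kif20a, a mitotic kinesin, and Mki67, the proliferation marker Ki-67, were at -1.01 ± 0.17 (adjusted p = 0.0566) and -1.06 ± 0.20 (adjusted p = 0.107). The DNA replication list also fell, with 28 of 28 members lower and a mean of -0.37 (camera adjusted p = 2.75e-20). Its adjusted p = 0.0894 with an estimated correlation; 1 member passed over all genes and 20 adjusted over the list alone. Uhrf1, Cdc6 and Mcm10, which act at replicating DNA, were at -0.61, -0.40 and -0.47. Beside both lists, neuron markers were 0.06 higher and oligodendrocyte markers were at -0.09 in TMZ, and the glioma and neural progenitor list was at -0.18, with Vim at -1.01 ± 0.23, Myc at -0.53 ± 0.11 and Nes at -0.30 ± 0.10. The mean level of the mitosis genes was 4.87 log2, below the median gene at 5.72.

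Interferon-stimulated genes were lower after TMZ as lists. In the type I interferon list 25 of 26 members were lower (mean -0.73, camera adjusted p = 6.64e-19, adjusted p = 0.228 with an estimated correlation). Over all genes 0 of its members passed in limma, and 20 passed adjusted over the list alone. Bst2, the antiviral tetherin (probe set 17510345), Herc6 and Mx1 were at -1.69 ± 0.45, -0.90 ± 0.19 and -0.49 ± 0.09. The interferon gamma list was at -0.72 with 19 of 20 members lower (camera adjusted p = 5.88e-09, adjusted p = 0.25 with an estimated correlation). Here 0 members passed over all genes and 6 adjusted over the list alone, with the immunity-related GTPase Irgm1 at -1.18 ± 0.32, Gbp3 at -1.04 ± 0.30 and Irf1 at -0.67 ± 0.20. Interferon gamma scores overlapped between the groups, with 0.36 for TMZ replicate 1 and -0.15 for Control replicate 3 (exact permutation p = 0.2), and the difference was -0.42 without Control replicate 2 and -1.08 without Control replicate 3. The MHC class I list (-0.41; Psmb8 -0.996, Tap1 -0.98), the MHC class II list (-0.39) and the complement and scavenger list (-0.36; C1qb -0.57, Cd68 -0.43) passed in camera with an adjusted p = 0.25, 0.25 and 0.266 with an estimated correlation. Within them H2-DMb1, a chaperone of class II peptide loading, passed over all genes (-0.49 ± 0.07, adjusted p = 0.041), and 2, 4 and 0 members passed adjusted over the list alone. Beside these lists, microglia markers were at -0.21 (Olfml3 -0.39, Fcrls -0.40) and TMZ replicate 2 had the lowest microglia score of all arrays, -0.27. Without that array the microglia difference was -0.12 and the MHC class II difference -0.18; without Control replicate 2 the MHC class II and class I differences were both -0.26, and MHC class I was at -0.63 without Control replicate 3. Scores of the type I interferon, MHC, complement and microglia lists also overlapped between TMZ and Control. Under the neuron covariate the differences were -0.23 for interferon gamma, -0.42 for type I interferon, -0.16 for MHC class I, -0.18 for MHC class II and -0.13 for complement and scavenger genes, and these lists stayed called.

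Smaller list differences after TMZ included cytotoxic lymphocytes (-0.23; Cxcr6 -0.54, Gzma -0.50), immediate early genes (-0.20; Dusp6 -0.37), natural killer cells (-0.15; Klra9 -0.51), monocytes and blood-derived macrophages (-0.15, median -0.10; Ly6c2 -0.70), inflammatory cytokines and NF-kB targets (-0.13; Tnf -0.29), dendritic cells (-0.12; Itgax -0.59) and checkpoint receptors (-0.11; Lag3 -0.41). Higher lists were endothelium (0.18; Slco1a4 0.56, Flt1 0.40, Vwf 0.56), choroid plexus and ependyma (0.12; Dynlrb2 0.48) and neurons (0.06; Snhg11 0.31). In total camera called 20 of 34 lists, 3 higher and 17 lower; with an estimated correlation it called 0, with an adjusted p from 0.0894 to 0.388, and fry called 3, mitosis, DNA replication and natural killer cells. The endothelium call was lost without TMZ replicate 2, whose score of 0.30 was the highest, and the mean difference was then 0.07; the choroid plexus call was lost without TMZ replicate 1 (0.03), and the natural killer cell call without TMZ replicate 2 (-0.13). The checkpoint call was lost without Control replicate 2 (-0.08) or TMZ replicate 2 (-0.06), the monocyte call without Control replicate 2 (-0.07), TMZ replicate 2 (-0.13) or TMZ replicate 3 (-0.11), and the glioma call without Control replicate 2 (-0.12). Without Control replicate 2 the immediate early gene difference was -0.12, and without TMZ replicate 2 the dendritic cell difference was -0.08. The oligodendrocyte call was lost without Control replicate 1 (-0.05) or TMZ replicate 2 or 3 (-0.06 for both), and the neuron call without Control replicate 1 (0.05), Control replicate 2 or TMZ replicate 3 (0.04 for both) or any Anti-PD-1 array (0.06). The neuron covariate ended the calls of inflammatory cytokines (-0.08), checkpoint receptors (-0.07), dendritic cells (-0.07), oligodendrocytes (-0.04), monocytes (0.00) and glioma and neural progenitors (-0.09); with it mitosis was at -0.57 and DNA replication at -0.28.

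Lists that were not called after TMZ included those tied to DNA damage. The p53 target list was at -0.06 (camera adjusted p = 0.322), the DNA repair list at -0.05 (0.267) and the apoptosis list at -0.06 (0.447). Cdkn1a, the p21 gene induced by p53, was at -0.23 ± 0.12 (adjusted p = 0.505), and Mgmt, whose product removes the methyl group that TMZ adds to guanine, at -0.08 ± 0.10 (adjusted p = 0.797). T cells were at -0.10 (adjusted p = 0.113), regulatory T cells at -0.02 (0.302), B cells at -0.07 (0.118), plasma cells at -0.07 (0.125) and alternatively activated macrophages at -0.20 (0.0573). Neutrophils (0.947), astrocytes (0.267), fibroblasts and pericytes (0.132), hypoxia (0.82), cholesterol biosynthesis (0.722) and blood cells (0.123) also missed the threshold, in adjusted p. Among single immune genes, Pdcd1 was at -0.27 ± 0.17, Cd274 at -0.14 ± 0.26, Cd8a at -0.12 ± 0.10, Ifng at -0.14 ± 0.08, Gzmb at -0.29 ± 0.23, Foxp3 at 0.20 ± 0.17 and P2ry12 at -0.12 ± 0.09, with adjusted p from 0.563 to 0.876.

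**Figure D1:**
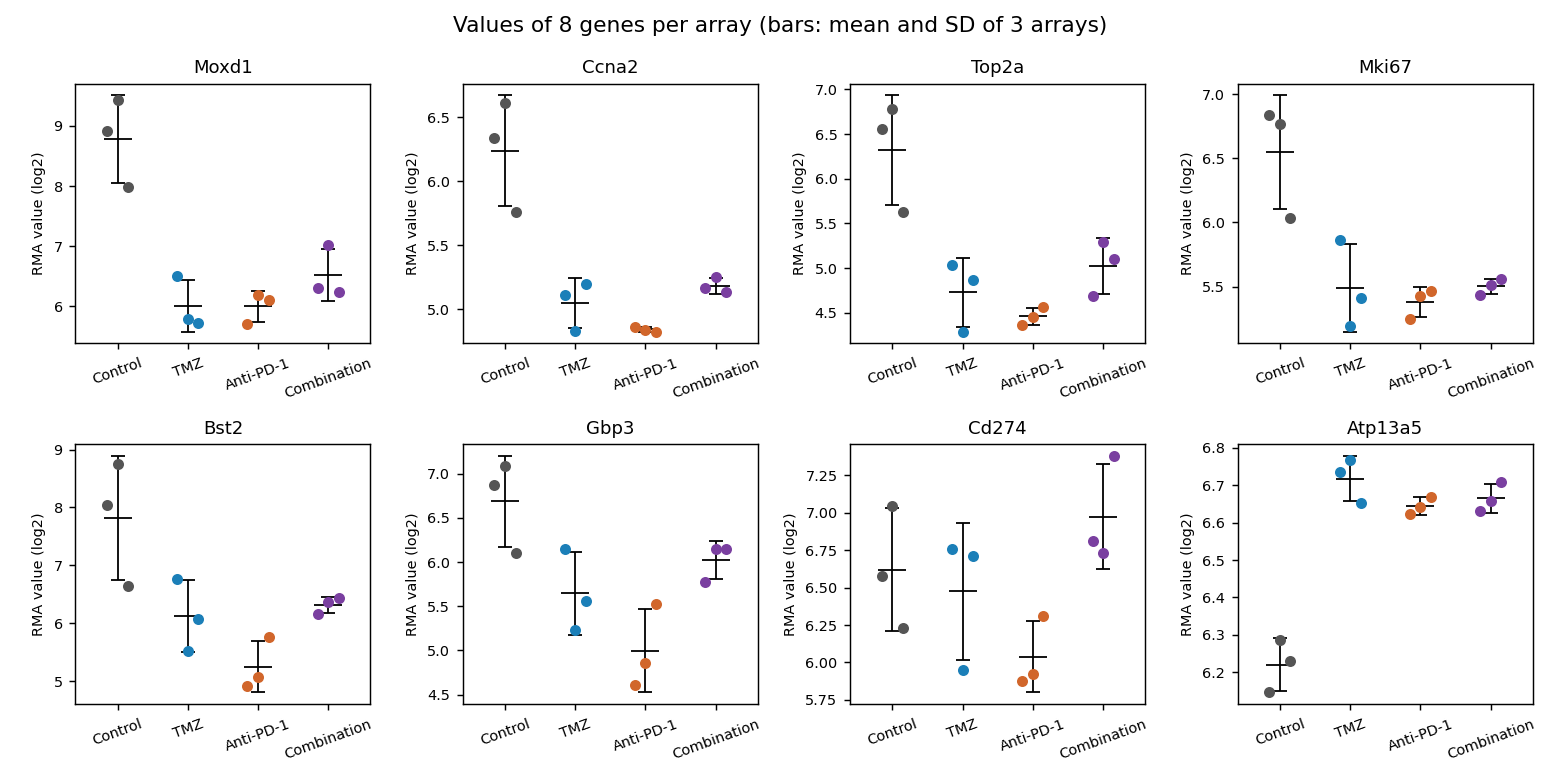
Log2 RMA signal (vertical axis) of 8 genes on each of the 12 arrays by group, with the group mean and SD (n = 3). Moxd1 averaged 8.78 in Control and between 6.00 and 6.52 in the treated groups, and Cd274 was lowest with Anti-PD-1 at 6.04 and highest in Combination at 6.97.

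Anti-PD-1 was compared with Control to see how blocking the receptor alone altered the tumours, and cell cycle and interferon-stimulated genes were lower after it. Their lists passed in camera at its preset correlation but not with an estimated correlation (camera adjusted p = 0.123 for mitosis and 0.146 for interferon gamma). Moxd1 was 6.86-fold lower, at 6.00 ± 0.26 against 8.78 ± 0.73 in Control (SD, n = 3; adjusted p = 0.0183). Bst2 fell 5.91-fold (log2 difference -2.56 ± 0.45 SE, adjusted p = 0.0495), Ifitm3, which restricts viral entry, fell 3.55-fold (-1.83 ± 0.30), and Gbp3, an interferon-induced guanylate-binding protein, fell 3.23-fold (-1.69 ± 0.30, adjusted p = 0.0495). Top2a, the topoisomerase that untangles replicated DNA, fell 3.63-fold (-1.86 ± 0.27, adjusted p = 0.0326), Ccna2 and Ect2 each fell 2.62-fold, and Mki67 fell 2.25-fold (adjusted p = 0.0472). The other named falls were galectin-1 gene Lgals1 (-1.46), Parp12 (-1.34), AI662270 (-1.28), Hmmr (-0.86) and Ccn1 (-0.73). The named rises were smaller: the noncoding RNA genes Pcsk2os1 (0.47 ± 0.08) and Kcnq1ot1 (0.45 ± 0.08), Atp13a5 (0.42 ± 0.06), the tuft cell factor Pou2f3 (0.40 ± 0.06) and the activin receptor gene Acvr2a (0.39 ± 0.07). In all of these the 3 Anti-PD-1 arrays lay on 1 side of the 3 Control arrays, which the naming rule required of the largest rises and falls.

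In total limma called 65 genes between Anti-PD-1 and Control, 18 higher and 47 lower, 16 of them of the classes not named; 2993 genes had an unadjusted p under 0.05. The count was 686 without Control replicate 3, 50 without TMZ replicate 1 and 1 without any of the other Control or Anti-PD-1 arrays, and it lay between 8 and 18 without any other array. It was 381 with a variance trend, 13 with the brain covariate, 2 when all probe sets were tested, and 0 when only the groups compared were fitted or with the neuron score as a covariate. Moxd1, Ccna2 and Hmmr passed in 7 of 12 fits that left out 1 array, and Bst2 and Gbp3 in 2 of 12, those without Control replicate 3 or TMZ replicate 1.

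The mitosis list fell with Anti-PD-1 as it did with TMZ: all 29 members were lower (mean -0.79, camera adjusted p = 8.23e-34; adjusted p = 0.123 with an estimated correlation and 0.0114 by fry). Over all genes 10 members passed, and 26 did adjusted over the list alone. Both falls were measured against the same Control arrays. Mean mitosis scores were -0.20 in TMZ and -0.22 in Anti-PD-1 against 0.57 in Control. The DNA replication list was at -0.35 with 27 of 28 members lower (camera adjusted p = 2.08e-17, adjusted p = 0.123 with an estimated correlation). Of its members, Rrm1, a subunit of ribonucleotide reductase, passed over all genes (-0.43 ± 0.08, adjusted p = 0.05) and 18 passed adjusted over the list alone, with Mcm3 at -0.80 ± 0.15. Beside these lists, neuron markers were 0.10 higher with 19 of 20 members up (camera adjusted p = 0.00157, adjusted p = 0.269 with an estimated correlation), oligodendrocyte markers were at -0.04 and astrocyte markers at -0.04. The glioma and neural progenitor list was at -0.25 (adjusted p = 0.146 with an estimated correlation), with Myc at -0.67 ± 0.11 (adjusted p = 0.0432), Nes at -0.52 ± 0.10 and Vim at -1.16 ± 0.23.

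The interferon gamma list had the largest mean difference of the 34 lists in this comparison, -1.27, with 19 of 20 members lower (camera adjusted p = 2.69e-16; adjusted p = 0.146 with an estimated correlation and 0.0341 by fry). Over all genes Gbp3 passed, and 16 members passed adjusted over the list alone, with Irgm1 at -1.65 ± 0.32, Gbp7 at -1.24 ± 0.28 and Gbp9 at -1.16 ± 0.27. The type I interferon list was at -1.003 with 26 of 26 members lower (camera adjusted p = 1.4e-24, adjusted p = 0.141 with an estimated correlation). Bst2 was the 1 member past the threshold over all genes, and 23 passed adjusted over the list alone, with Zbp1 at -1.76 ± 0.33 and Ifit1 at -1.61 ± 0.31. The MHC class I list (-0.63; Tap1 -1.36, Psmb8 -1.34, H2-T23 -0.94), the MHC class II list (-0.57, median -0.37; Ifi30 -1.08, Ctss -0.75) and the complement and scavenger list (-0.47; Cfb -0.82, C3ar1 -0.72) were also lower, with an adjusted p = 0.148, 0.146 and 0.19 with an estimated correlation. Over all genes 0 of their members passed in limma, and 13, 7 and 14 passed adjusted over the list alone. Beside them, microglia markers were at -0.18 (Crybb1 -0.47, Olfml3 -0.43, Trem2 -0.29), monocyte markers at -0.29 and alternatively activated macrophage markers at -0.30. The medians of the last 2 lists were -0.14 and -0.12, and without Gpnmb (-2.83) the mean of the macrophage list was -0.14. Over the alternatives the mean of the macrophage list ran from -0.76 to -0.13. After adding the neuron covariate the differences were -0.48 for interferon gamma, -0.49 for type I interferon, -0.24 for MHC class I, -0.22 for MHC class II, -0.45 for mitosis and -0.20 for DNA replication, all still called.

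Among those myeloid lists Plac8 fell by 0.69 on the log2 scale (SE 0.10, adjusted p = 0.0326), and Gpnmb, a glycoprotein of tumour-associated macrophages, was at -2.83 ± 0.55 (adjusted p = 0.0561). Immediate early genes were at -0.31 (Dusp6 -0.51, Nr4a1 -0.50, Junb -0.46), dendritic cells at -0.19 (Irf8 -0.70), cytotoxic lymphocytes at -0.15 (Cst7 -0.88), inflammatory cytokines at -0.15 (Il1b -0.52) and checkpoint receptors at -0.14 (Tnfrsf9 -0.37). Camera called 17 of 34 lists, 1 higher and 16 lower; 0 were called with an estimated correlation (adjusted p from 0.123 to 0.287) and 13 by fry. The cytotoxic lymphocyte call was lost without Control replicate 2 or Anti-PD-1 replicate 1, with a difference of -0.09 in both cases. The other 16 calls held whichever array was left out, but the differences depended on Control. That of interferon gamma ran from -1.64 to -0.98. Control replicate 3 scored -0.15 for interferon gamma and -0.113 for MHC class I, against -0.27 and -0.117 for Anti-PD-1 replicate 3. MHC class II and complement scores overlapped between the groups (exact permutation p = 0.2 for both). Camera called 11 lists under the neuron covariate, some of which were not called without it. The calls of alternatively activated macrophages (-0.13), complement (-0.10), dendritic cells (-0.10), inflammatory cytokines (-0.08), checkpoint receptors (-0.08), microglia (-0.07), monocytes (-0.04) and cytotoxic lymphocytes (0.01) were lost. T cells were at -0.09 (camera adjusted p = 0.104), p53 targets at -0.07 (0.466) and DNA repair at -0.04 (0.319). Cd274, which encodes the PD-1 ligand, was at -0.58 ± 0.26 (adjusted p = 0.355), Pdcd1 at -0.28 ± 0.17, Cd8a at 0.02 ± 0.10, Ifng at -0.15 ± 0.08, Gzmb at -0.25 ± 0.23, Foxp3 at -0.02 ± 0.17, Cdkn1a at -0.46 ± 0.12, Mgmt at -0.02 ± 0.10 and P2ry12 at -0.05 ± 0.09.

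**Figure D2:**
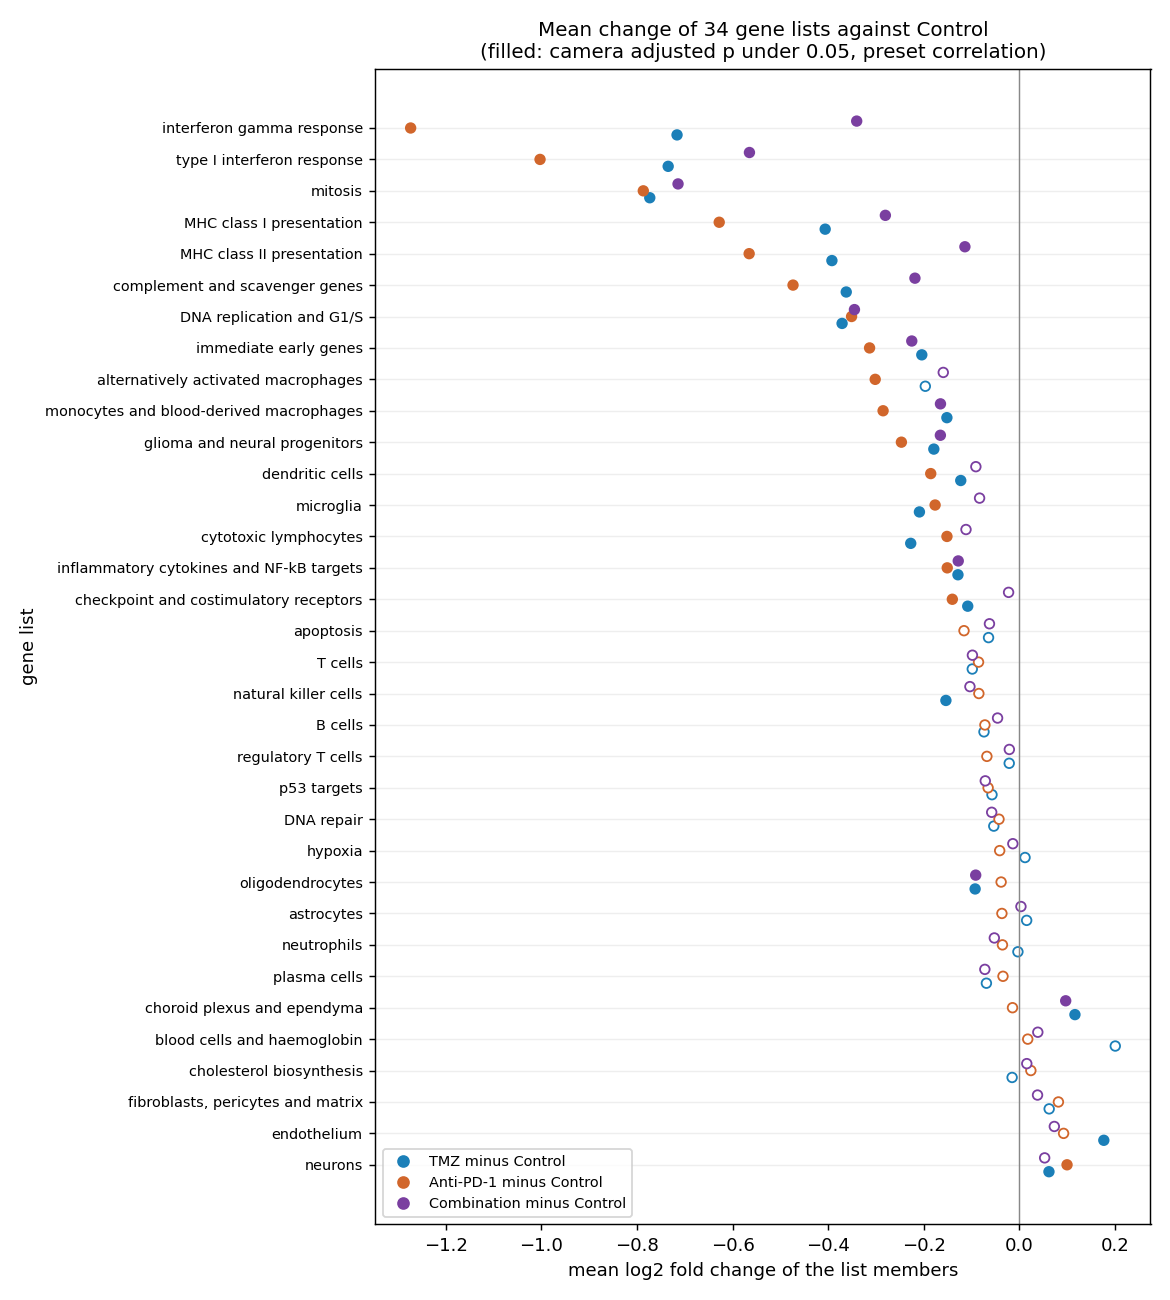
Mean log2 difference from Control (horizontal axis) of the 34 gene lists (vertical axis) in the TMZ, Anti-PD-1 and Combination groups, 3 arrays each; filled symbols mark a camera adjusted p under 0.05 at the preset correlation. The mitosis list lay at -0.77, -0.79 and -0.71, and the interferon gamma list at -0.72, -1.27 and -0.34.

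Combination was compared with Control to see how both agents together altered the tumours. Over all genes 0 passed in limma. Neb, the nebulin gene, was at -0.63 ± 0.08 and Atp13a5 at 0.45 ± 0.06 (adjusted p = 0.0639 for both). Moxd1 was at -2.25 ± 0.34, Ect2 at -1.28 ± 0.19, Hmmr at -0.74 ± 0.11 and Aurka, a mitotic kinase, at -0.67 ± 0.10 (adjusted p = 0.0725). On the higher side the zinc finger genes Zfp932 (0.87 ± 0.14, adjusted p = 0.107) and Zfp788 (0.33 ± 0.07), Gsdma3 (0.37 ± 0.07) and Pnma3 (0.32 ± 0.07) missed the threshold. Every one of these genes had its 3 Combination arrays on 1 side of the 3 Control arrays, which the naming rule required. The unadjusted p was under 0.05 for 2576 genes. Limma called 42 genes with a variance trend, 17 with array weights and 3 without dim genes. It called 282 when Control replicate 3 was left out, 3 when Combination replicate 2 was left out and 0 without any other array.

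The mitosis list fell in Combination, with 29 of 29 members lower (mean -0.71, camera adjusted p = 2.17e-32; adjusted p = 0.138 with an estimated correlation and 0.0138 by fry), and so did the DNA replication list, with 28 of 28 members lower (-0.35, camera adjusted p = 1.24e-17, adjusted p = 0.138 with an estimated correlation). Both falls were again measured against the Control arrays used for TMZ and Anti-PD-1. Over all genes 0 members of these lists passed in limma. Adjusted over the list alone, 27 and 15 did, with Ccna2 at -1.05 ± 0.17, Cdc6 at -0.51 ± 0.08 and Mcm5 at -0.94 ± 0.20. Beside them, oligodendrocyte markers were at -0.09 (Gjc3 -0.28), choroid plexus and ependyma markers at 0.10 (Enkur 0.22) and glioma and neural progenitor genes at -0.17 (Nes -0.44, Vim -0.85), with an adjusted p = 0.506, 0.506 and 0.468 with an estimated correlation. The type I interferon list was at -0.56 with 26 of 26 members lower (camera adjusted p = 3e-12, adjusted p = 0.468 with an estimated correlation; 0 passed over all genes, 4 adjusted over the list alone), with Bst2 at -1.50 ± 0.45. The interferon gamma list was at -0.34 (adjusted p = 0.506 with an estimated correlation; 0 passed over all genes, 1 adjusted over the list alone), the MHC class I list at -0.28, the complement and scavenger list at -0.22 and the MHC class II list at -0.11. Immediate early genes were at -0.23, monocytes at -0.17 and inflammatory cytokines at -0.13, and microglia markers (-0.08, camera adjusted p = 0.0691) and neuron markers (0.05, 0.13) were not called. Camera called 13 lists, 1 higher and 12 lower, against 0 with an estimated correlation and 2 by fry; the count was 6 without Control replicate 2 and 8 without Combination replicate 1. Without Control replicate 2 the interferon gamma difference was -0.05 and that of MHC class II turned to 0.02, and the MHC class I (-0.13), complement (-0.11), glioma (-0.11), monocyte (-0.08) and inflammatory cytokine (-0.10) calls were lost; type I interferon was then at -0.38 and immediate early genes at -0.14. Without Control replicate 3 the interferon gamma difference was -0.71. Leaving out a single array took MHC class I as low as -0.50, complement to -0.39, MHC class II to -0.31 and monocytes to -0.26. With the neuron score as a covariate the interferon gamma and MHC class II differences were 0.08 and 0.07, and the complement (-0.02) and MHC class I (-0.07) calls were among those lost. The interferon gamma (-0.19), MHC class II (-0.06), complement (-0.17), glioma (-0.15) and monocyte (-0.11) calls were lost without Combination replicate 1, and the MHC class II (-0.06), complement (-0.16) and oligodendrocyte (-0.05) calls without Control replicate 1. The oligodendrocyte (-0.06) and MHC class II (-0.13) calls also needed Combination replicate 2, and the choroid plexus call Control replicates 2 and 3 and Combination replicate 3 (0.05 without it). Cd274 was at 0.36 ± 0.26, Pdcd1 at -0.11 ± 0.17, Cd8a at 0.01 ± 0.10, Ifng at -0.07 ± 0.08, Gzmb at -0.33 ± 0.23, Foxp3 at -0.17 ± 0.17, Cdkn1a at -0.46 ± 0.12, Mgmt at -0.13 ± 0.10, Mki67 at -1.05 ± 0.20 and P2ry12 at 0.03 ± 0.09.

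Combination was compared with Anti-PD-1 alone to see what adding TMZ changed, and the interferon gamma list was higher in Combination. Of its 20 members 18 were higher, with a mean difference of 0.93 (camera adjusted p = 1.39e-14; adjusted p = 0.432 with an estimated correlation). The GTPase genes Iigp1, Irgm2 and Gbp3 were 1.87 ± 0.55, 1.36 ± 0.42 and 1.02 ± 0.30 higher (SE, n = 3), and Cd274 was 0.94 ± 0.26 higher. Over all genes 0 members passed in limma, and 10 passed adjusted over the list alone. Scores averaged 0.24 ± 0.25 (SD, n = 3) in Combination and -0.69 ± 0.41 in Anti-PD-1 without overlap (exact permutation p = 0.1, the smallest that 3 against 3 arrays allow). The MHC class II list (0.45; H2-Ab1 1.505 ± 0.73), the type I interferon list (0.44; Oas1g 1.29 ± 0.39, Isg15 0.62 ± 0.23), the MHC class I list (0.35; Tap1 0.84 ± 0.27, H2-T23 0.73 ± 0.23) and the complement and scavenger list (0.26; C4b 0.65 ± 0.31) were also higher in camera, each with an adjusted p = 0.432 with an estimated correlation. In these lists 0 members passed over all genes or adjusted over the list alone. Beside them, microglia markers were 0.09 higher (P2ry13 0.36), checkpoint receptors 0.12 (0.07 without Cd274), dendritic cells 0.09 (median 0.04), choroid plexus 0.11, glioma and neural progenitors 0.08 and immediate early genes 0.09, and neuron markers were at -0.05; T cells (-0.01) and cytotoxic lymphocytes (0.04) were not called. The mitosis list differed by 0.07 (camera adjusted p = 0.072).

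No single gene separated Combination from Anti-PD-1 in limma, which called 0 of 22180 in every setting; 1089 had an unadjusted p under 0.05. The smallest p values belonged to Prss55 (-0.44 ± 0.07, adjusted p = 0.325), Pou2f3 (-0.33 ± 0.06), Msc (-0.40), the cytokine gene Il7 (-0.32) and Zgrf1 (-0.39) on the lower side and to Esp38 (0.39 ± 0.08, adjusted p = 0.581), the RNA sensor gene Tlr13 (0.59 ± 0.13), Ceacam2 (0.42), the clotting factor gene F5 (0.53) and Aass (0.42) on the higher. Camera called 12 lists, 11 higher and 1 lower, against 0 with an estimated correlation and 0 by fry, and the count was 6 without Combination replicate 3 and 7 without Anti-PD-1 replicate 1. The interferon gamma, type I interferon, MHC and complement calls held whichever array was left out, the first with differences from 0.73 to 1.15; MHC class II was at 0.26 without Anti-PD-1 replicate 1. With the neuron score as a covariate the interferon gamma difference was 0.56, MHC class II was at 0.29, type I interferon at 0.20 and MHC class I at 0.16, and the complement call (0.08) was lost. The checkpoint, glioma and microglia calls were lost without Anti-PD-1 replicate 1 or Combination replicate 3. The dendritic cell call was lost without any Anti-PD-1 array or Combination replicate 1 or 3 (0.08 to 0.11), and the neuron call without any Anti-PD-1 array, Control replicate 2 or Combination replicate 2 or 3 (-0.05 to -0.03). Also lost were the choroid plexus call without Combination replicate 3 (0.06), and the immediate early gene call without Anti-PD-1 replicate 3 (0.06) or Combination replicate 1, where its difference was -0.00.

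Combination was compared with TMZ alone to see what adding the antibody changed, and camera called 9 lists at its preset correlation, each with an adjusted p = 0.937 with an estimated correlation. The interferon gamma list was 0.38 higher (Iigp1 0.84 ± 0.55, Irf1 0.32 ± 0.20), MHC class II 0.28 (median 0.15; H2-DMb1 0.29 ± 0.07), type I interferon 0.17 (Mx1 0.27 ± 0.09), complement and scavenger genes 0.14, MHC class I 0.13 (median 0.08), microglia 0.13 (Siglech 0.33 ± 0.08), cytotoxic lymphocytes 0.12 (median 0.07; Klrd1 0.27 ± 0.09) and checkpoint receptors 0.09 (Cd96 0.37 ± 0.10), and endothelium was at -0.10 (Vwf -0.41). Of the 12 immune cell lists, 9 were not called, among them T cells (0.00), regulatory T cells (0.00), plasma cells (-0.00), monocytes (-0.01) and neutrophils (-0.05). The count of called lists was 0 without TMZ replicate 2 or Combination replicate 3, 3 without Combination replicate 2 and 5 without TMZ replicate 3. Without TMZ replicate 2 the differences were 0.16 for interferon gamma, 0.06 for MHC class II, 0.05 for type I interferon, 0.05 for complement, 0.05 for MHC class I, 0.04 for microglia, 0.06 for cytotoxic lymphocytes, 0.04 for checkpoint receptors and 0.00 for endothelium. Checkpoint receptors were at 0.04 without Combination replicate 3 as well. Without other single arrays the differences reached 0.62 for interferon gamma, 0.46 for MHC class II and 0.30 for type I interferon. They reached 0.27 for complement, 0.21 for MHC class I, 0.21 for microglia, 0.17 for cytotoxic lymphocytes, 0.12 for checkpoint receptors and -0.17 for endothelium. The neuron covariate ended the calls of MHC class I (0.09), cytotoxic lymphocytes (0.10) and checkpoint receptors (0.08). Over all genes limma called 0 in every setting, with 930 genes at an unadjusted p under 0.05. The smallest p values belonged to Gsdmc2 (-0.65 ± 0.11) and Fam71a (-0.55 ± 0.10), both with adjusted p = 0.67, and to Micalcl (-0.30), Msc (-0.43), Hnrnpa1l2-ps2 (-0.48), Stx11 (0.31), Defb34 (0.34), Map3k14 (0.41), Katna1 (0.41) and Pbld1 (0.26).

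TMZ was also compared directly with Anti-PD-1, and the interferon gamma list was 0.56 higher with TMZ (Gbp4 1.22 ± 0.44, Irgm2 0.99 ± 0.42; camera adjusted p = 2.66e-05, adjusted p = 0.614 with an estimated correlation). The type I interferon list was 0.27 higher, MHC class I 0.22, monocytes 0.13 (Plac8 0.28 ± 0.10), choroid plexus and ependyma 0.13, immediate early genes 0.11 (Nr4a1 0.37 ± 0.12), endothelium 0.08 and glioma and neural progenitors 0.07, each with an adjusted p = 0.614 with an estimated correlation. Mitosis differed by 0.01 (camera adjusted p = 0.898). Camera called these 8 lists, fry 0; the count was 3 without Anti-PD-1 replicate 1, 4 without TMZ replicate 1 and 5 without Anti-PD-1 replicate 2. The interferon gamma call was lost without TMZ replicate 1 (0.31) and with the neuron score as a covariate (0.26), and the difference was 0.36 without Anti-PD-1 replicate 1. The covariate ended all 8 calls, with type I interferon and MHC class I both at 0.07. Also lost were the type I interferon and MHC class I calls without TMZ replicate 1 (0.13 and 0.14) or Anti-PD-1 replicate 1 (0.18 and 0.12), and the choroid plexus call without TMZ replicate 1 (0.04). The endothelium call was lost without TMZ replicate 2 (-0.02), Anti-PD-1 replicate 1 (0.07) or Anti-PD-1 replicate 2 (0.10), and the immediate early gene call without TMZ replicate 2 (0.04) or Anti-PD-1 replicate 3 (0.08). The glioma call was lost without TMZ replicate 1 (0.01), Anti-PD-1 replicate 1 (0.04), or Anti-PD-1 replicate 2 or any Combination array (0.07). The monocyte call was lost without TMZ replicate 1 (0.07), Anti-PD-1 replicate 1 (0.10), Anti-PD-1 replicate 2 (0.12), or Combination replicate 1 or 3 (0.13). Limma called 0 genes in every setting, with 1000 at an unadjusted p under 0.05; Wfikkn2 (-0.60 ± 0.10), Pou2f3 (-0.29), Nrg3os (-0.51), Krt6a (-0.40), Gdf7 (-0.32), Btbd35f17 (0.52 ± 0.11), Gsdmc2 (0.49), Hnrnpa1l2-ps2 (0.44), Tmem132cos (0.36) and Inca1 (0.35) had the smallest p values.

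**Figure D3:**
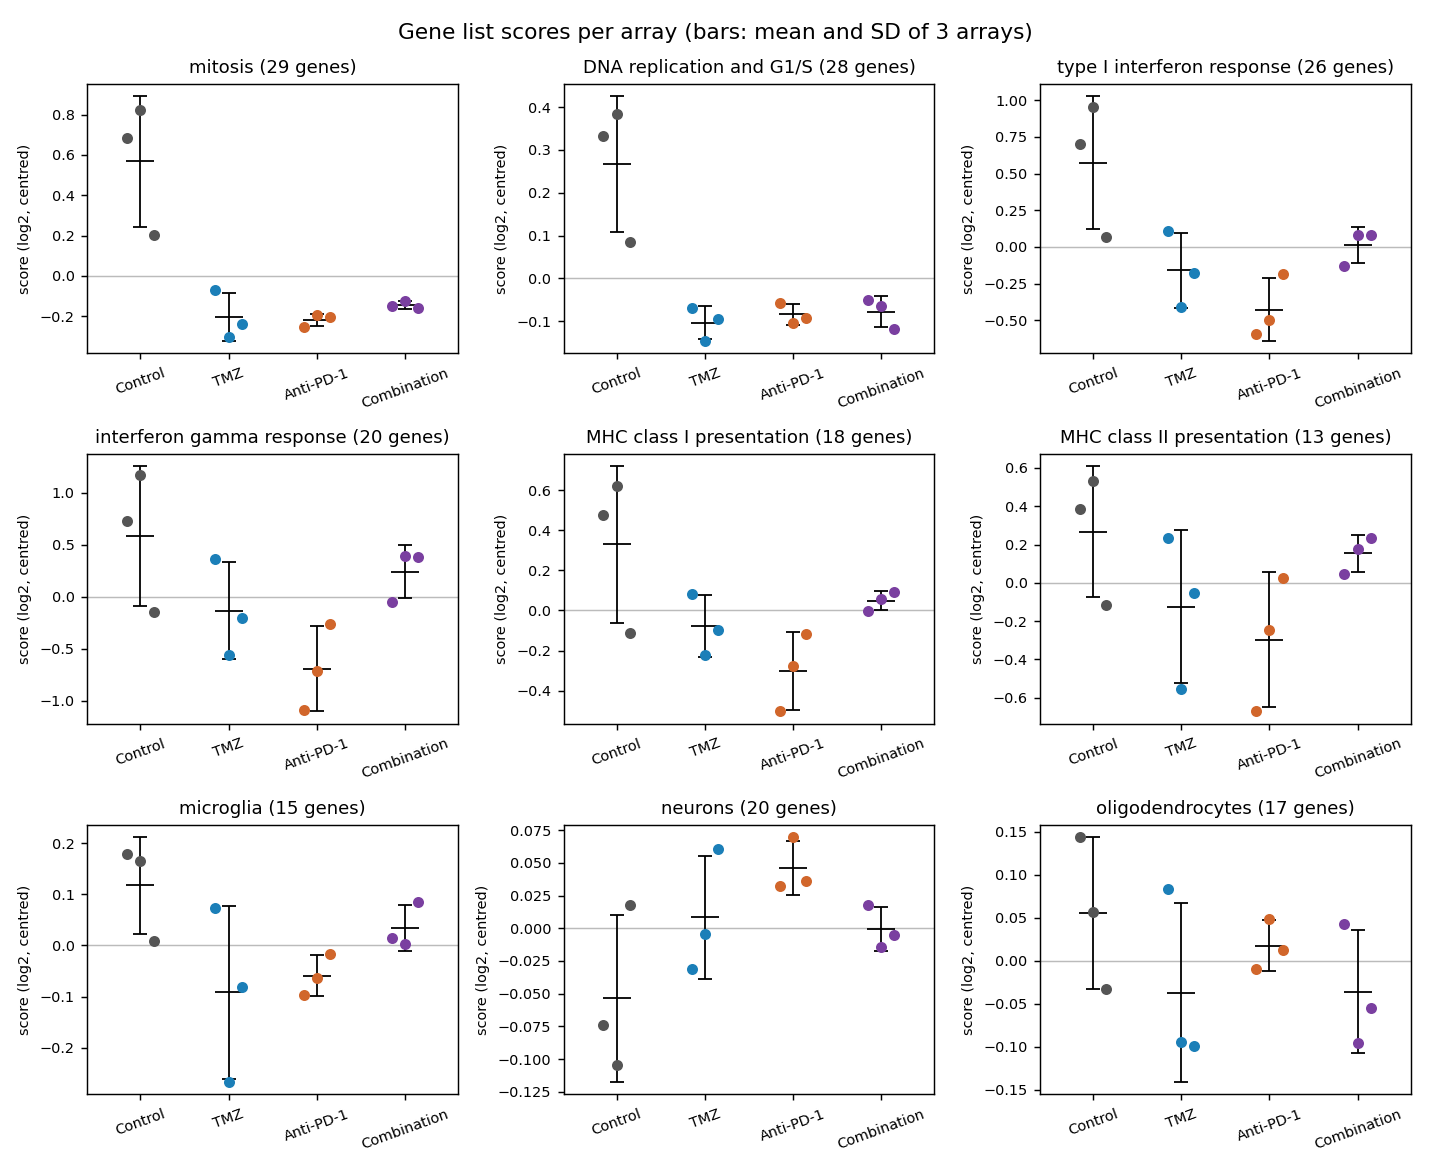
Scores of 9 gene lists (vertical axis, mean log2 deviation from each gene's mean) on each of the 12 arrays by group, with the group mean and SD (n = 3). Mitosis scores were 0.68, 0.82 and 0.20 in Control and at most -0.07 in treated arrays, and interferon gamma scores ran from -1.09 to -0.27 with Anti-PD-1 and from -0.05 to 0.39 in Combination.

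The interaction asked whether both agents together differed from the sum of their single effects. The Control mean enters this term and the differences from Control with opposite signs, so that genes picked for such a difference tend to have a term of the opposite sign without any interaction. Moxd1 had an interaction of 3.29 ± 0.48, Ccna2 of 1.53 ± 0.24, Car6 of 1.36 ± 0.19, Atp13a5 of -0.48 ± 0.08 and Inca1 of -0.63 ± 0.12, with adjusted p from 0.113 to 0.193. Stx11 (0.62), Esp38 (0.69), Ddit4l (-0.48), Scn9a (-0.55) and Pou2f3 (-0.44) also missed the threshold. The list means were 1.65 for interferon gamma (Iigp1 3.09 ± 0.78, Gbp3 2.06 ± 0.42), 1.17 for type I interferon (Mx1 0.71 ± 0.12) and 0.85 for mitosis (Top2a 2.16 ± 0.39), with adjusted p = 0.147 with an estimated correlation for each. In those lists 0 members passed over all genes, and 17, 20 and 26 passed adjusted over the list alone. Under the neuron covariate these terms were 0.79, 0.61 and 0.48. Camera called 18 lists, 16 higher and 2 lower (neurons -0.11 and endothelium -0.20, the latter -0.09 and not called without TMZ replicate 2), against 0 with an estimated correlation and 0 by fry. Limma called 1 gene, the predicted gene 3830403N18Rik, and 1978 genes had an unadjusted p under 0.05; the count was 198 without Control replicate 3, 0 without TMZ replicate 2 or Anti-PD-1 replicate 1 or 2, and 2 without TMZ replicate 1 or 3. The F test over the 4 groups called 1 gene, again 3830403N18Rik (adjusted p = 0.00765), named after its value was seen because it was the only call, with 2230 genes at an unadjusted p under 0.05. That count was 245 without Control replicate 3, 0 without Control replicate 1 or 2, 2 without TMZ replicate 1 and 4 without Combination replicate 2.

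The changes after TMZ and after Anti-PD-1 were compared with each other, although both were measured against the same Control arrays. Of the genes called, 3 higher and 13 lower ones were shared. In 100 simulations without any effect, in which whole residual arrays shared their controls, equal numbers of top genes shared on average 0.09 higher (at most 2) and 0.64 lower ones (at most 6); independent lists of these sizes, without shared controls, share 0.00325 and 0.0381. All 22 genes called after TMZ, 4 higher and 18 lower, had the same sign after Anti-PD-1, where the simulations gave 20.98 on average, from 0 to 22. Across the 22180 genes, which are not independent replicates, the log2 differences from Control had a correlation of 0.773. Because the Control arrays are shared, 100 simulations without any effect gave a mean correlation of 0.4998, from 0.473 to 0.529, with genes drawn independently, and of 0.452, from -0.284 to 0.804, with whole residual arrays, a range that includes the observed value. With different, and therefore fewer, Control arrays for each treatment the mean correlation over 6 choices was 0.412, from 0.182 to 0.536. The covariance of the differences was 0.0241, against 0.00692 on average in the residual array simulations, from -0.00207 to 0.0169, and 0.0162 with different Control arrays. With the shared Control arrays but without genes below the median level the correlation was 0.869, and no simulation was made for that set.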

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

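The tests of the 3 patterns weighed below and the comparison of all treated arrays with Control were chosen after the results were seen, whereas the counts over other splits of the arrays in the planned comparisons were planned before. Over all genes, the interaction term passed for 3830403N18Rik, at 1.33 ± 0.13 log2 (SE, adjusted p = 0.00909). Its means were 3.79 in Control, 2.83 in TMZ, 2.68 in Anti-PD-1 and 3.05 in Combination (n = 3 each), all below the median gene at 5.72, and the call was lost with the neuron score as a covariate (0 genes) and without TMZ replicate 2 or Anti-PD-1 replicate 1 or 2. Among 100 splits of the arrays into groups of the same sizes, the real one included and the others random, 6 gave at least 1 gene for the interaction (real value 1, highest other 1) and 6 gave at least 1 gene for the F test (real value 1, highest other 2), so chance is not excluded for either.

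The interaction term also passed for 18 lists in camera at its preset correlation. The mean terms were 1.65 for interferon gamma, 1.17 for type I interferon, 0.85 for mitosis, 0.84 for MHC class II, 0.75 for MHC class I and 0.62 for complement and scavenger genes. They were 0.38 for DNA replication, 0.34 for alternatively activated macrophages (median 0.11, and 0.14 without Gpnmb), 0.30 for microglia, 0.29 for immediate early genes, 0.27 for cytotoxic lymphocytes, 0.27 for monocytes (median 0.18), 0.26 for glioma and neural progenitors, 0.23 for checkpoint receptors, 0.22 for dendritic cells and 0.15 for inflammatory cytokines (median 0.09). Neurons (-0.11) and endothelium (-0.20, median -0.13) had negative terms. With an estimated correlation 0 lists were called, with an adjusted p from 0.147 to 0.295, and fry called 0. The monocyte call was lost without Control replicate 2 (0.19), the alternatively activated macrophage call without TMZ replicate 3 (0.30) or Combination replicate 2 (0.28), and the endothelium call without TMZ replicate 2 (-0.09). With the neuron score as a covariate the terms were 0.79 for interferon gamma, 0.61 for type I interferon, 0.48 for mitosis, 0.47 for MHC class II, 0.33 for MHC class I, 0.21 for DNA replication and 0.21 for complement. The calls of cytotoxic lymphocytes (0.09), monocytes (0.00), alternatively activated macrophages (0.15), dendritic cells (0.12), inflammatory cytokines (0.07) and glioma and neural progenitors (0.11) were then lost. Over the same 100 splits, 8 gave 18 or more lists, the real one included, the highest other 24, so chance is not excluded.

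For the comparisons of 3 arrays with 3 there are 10 splits, too few for a share under 0.05. The gene counts were 22 for TMZ (highest other split 1) and 65 for Anti-PD-1 (highest other 0) against Control, and 0 (highest other 0) for Combination against Control, TMZ or Anti-PD-1 and for TMZ against Anti-PD-1. The list counts against Control were 20 for TMZ (highest other 19), 17 for Anti-PD-1 (18) and 13 for Combination (15). Between treated groups they were 9 for Combination against TMZ (17), 12 for Combination against Anti-PD-1 (12) and 8 for TMZ against Anti-PD-1 (12). Single outlying arrays were not tested within groups of 3; array weights estimated from the fit ran from 0.678 for Control replicate 3 to 1.36 for Anti-PD-1 replicate 2.

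Mitosis genes were lower in the treated arrays than in Control, with a mean difference of -0.76 ± 0.12 log2 (SE) over 29 genes. Of these, 21 passed over all genes and 29 adjusted over the list alone. This SE, and that under the neuron covariate, come from fits of the scores with 1 spread for all groups. Control scores varied most, with an SD of 0.32 against 0.12 in TMZ, 0.03 in Anti-PD-1 and 0.02 in Combination, so both may be too small. That 1 Control array decides the mitosis difference is argued against. The smallest change on leaving out a Control array was -0.63, and the lowest Control score (0.20) lay above the highest treated score (-0.07). Less tumour with more brain tissue of the same make-up stays open: neuron markers were 0.07 higher (exact p = 0.0364) and oligodendrocyte markers at -0.07 (exact p = 0.164), a difference with an exact p = 0.0409, not adjusted; their mean differed by -0.00137, so the planned brain covariate (-0.76 with it) had nothing to remove here. More neuron-rich tissue on the treated arrays may account for part of it: with the neuron score as a covariate the difference was -0.52 ± 0.10. Limma then called 0 genes in place of 197, but lost calls alone do not show how far the differences shrank. The glioma and neural progenitor list was also lower, at -0.20, with 3 members called over all genes (exact p = 0.00909, exact adjusted p = 0.0515). Less tumour could give such a fall too, which was not tested. Neither tissue explanation can be told apart from slower division, because high baselines of tissue markers hide a small change of share. Snap25 and Mobp, the most abundant neuron and oligodendrocyte markers, averaged 12.22 and 10.72 log2 in Control.

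Interferon gamma genes were lower with Anti-PD-1 alone than in Combination, by 0.93 ± 0.28 log2 (SE). Fewer microglia on the Anti-PD-1 arrays are argued against as the whole cause, since microglia markers (Selplg, the most abundant, at 8.00 against 8.11) differed by 0.093 and the gap between both lists was 0.84 ± 0.26. That 1 Anti-PD-1 array decides is argued against by the smallest difference on leaving one out, 0.73. For the tissue gradient of the mitosis list, the mitosis difference was 0.073 ± 0.02, below the 0.288 set as the least needed. That bound is itself an estimate whose error was not counted, so the tissue gradient stays open. More neuron-rich tissue on the Anti-PD-1 arrays may account for part, with a difference of 0.56 left under the neuron covariate. The other immune cell lists differed by -0.04 (plasma cells) to 0.14 (alternatively activated macrophages). Their gaps to the interferon gamma list were not tested, nor was an effect of TMZ on interferon signalling. The interferon gamma difference itself is a hypothesis. It had a camera adjusted p = 0.432 with an estimated correlation, and limma called 0 single genes, with 1089 at an unadjusted p under 0.05.

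The interaction ran opposite to the change of the treated groups from Control in 18 of 18 called lists, with a slope of -1.63 over the 34 lists. Array noise alone gives such a slope, because the Control mean enters both values with opposite sign: 36 of 100 splits, the real one included, had a slope as low, and the other splits averaged -1.10. The slope therefore shows neither a joint effect below the sum of both agents nor Control arrays set apart for a reason other than treatment. These cannot be told apart here, since the Control group is 1 set of arrays and the labels give no date or batch.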

How the results depend on the processing

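The fit without Control replicate 3 and TMZ replicate 2 together, the neuron covariate and the comparison of all treated arrays with Control were chosen after the data were seen; all other alternatives were planned. Among named genes, 54 of 491 results passed the threshold, and all 1358 of their values under the alternatives kept their sign. Because these genes were selected for separated groups or small p values in the same arrays, kept signs say little about stability. Of 12442 values, 11396 stayed on the same side of the threshold, 698 lost it, 320 gained it and 28, past it in neither case, changed sign. The 116 list calls kept side and sign in 2078 of 2523 values, 435 lost the threshold and 10 reversed. Counts of genes and lists depended more on the settings, and except where stated the cause was not tested.

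Of the gene counts, those for Combination against TMZ, Combination against Anti-PD-1 and TMZ against Anti-PD-1 were 0 in all settings. The others, in the order TMZ, Anti-PD-1 and Combination against Control, interaction, F test and all treated arrays, were 22, 65, 0, 1, 1 and 197. With a variance trend they were 113, 381, 42, 12, 90 and 677. Array weights gave 38, 260 and 17 for the treatments, 9 for the F test and 371 for all treated arrays; Control replicate 3 had the lowest weight, 0.678. Without dim genes they were 14, 205, 3, 0, 2 and 413, with fewer genes tested. Testing all probe sets gave 1, 2, 0, 0, 0 and 40, with more features in the adjustment. Robust variances gave 14 for TMZ and 33 for Anti-PD-1, median centring 43 for Anti-PD-1, and averaged probe sets 4 for the F test. The replicate block gave 4 for TMZ, 20 for Anti-PD-1 and 5 for the F test. The brain covariate gave 1 for TMZ, 13 for Anti-PD-1 and 121 for all treated arrays, and a 1.5-fold threshold 89 for the last by adding a condition. Fitting only the groups compared gave 0 for TMZ and 0 for Anti-PD-1. That fit has fewer arrays to estimate the spread and also leaves out groups of smaller spread. The fit over all arrays uses 1 spread per gene, although Control could vary more. Mitosis scores had an SD of 0.32 in Control, 0.12 in TMZ, 0.03 in Anti-PD-1 and 0.02 in Combination. MHC class II scores went the other way for TMZ, with 0.34 in Control and 0.40 in TMZ. The neuron covariate gave 0 for each of the 6 counts. Without both arrays that stood apart the 6 counts were 112, 619, 221, 68, 158 and 662.

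Leaving out each array in turn gave 0 to 363 genes for TMZ, 1 to 686 for Anti-PD-1, 0 to 282 for Combination, 0 to 198 for the interaction, 0 to 245 for the F test and 1 to 838 for all treated arrays, each highest without Control replicate 3. List counts ranged from 6 to 16 for Combination against Control, 0 to 11 against TMZ and 6 to 13 against Anti-PD-1, and from 3 to 11 for TMZ against Anti-PD-1; the other list counts stayed within 1.5 times.

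With an estimated correlation camera called 0 lists in all 8 comparisons. Fry called 3 for TMZ, 2 for Combination and 7 for all treated arrays against Control, and 0 for Combination against TMZ, Combination against Anti-PD-1, TMZ against Anti-PD-1 and the interaction. Without dim genes, 13 lists were called for TMZ and 5 for Combination against TMZ, and without both arrays that stood apart 0 for Combination against TMZ. Under the neuron covariate camera called 11 lists for Anti-PD-1, 6 for Combination and 11 for all treated arrays against Control, 5 for Combination against Anti-PD-1 and 3 for TMZ against Anti-PD-1. For Anti-PD-1 against Control and TMZ against Anti-PD-1 these counts include lists not called without the covariate. The covariate reversed the monocyte difference for TMZ (0.00238), that of cytotoxic lymphocytes for Anti-PD-1 (0.00645) and those of interferon gamma (0.0777) and MHC class II (0.067) for Combination against Control. The other 6 reversed list differences were MHC class II in Combination against Control without Control replicate 2 (0.0193; range without single arrays -0.306 to 0.0193), immediate early genes in Combination against Anti-PD-1 without Combination replicate 1 (-0.00461; range -0.00461 to 0.144), and endothelium without TMZ replicate 2, alone or with Control replicate 3, in Combination against TMZ (0.00133; range -0.169 to 0.00133) and TMZ against Anti-PD-1 (-0.0207; range -0.0207 to 0.15).

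The correlation of 0.773 between both agents' effects was 0.869 without dim genes, 0.719 with the neuron covariate, 0.412 with different Control arrays and 0.691 to 0.853 without single arrays. Different Control arrays remove the shared error but also leave fewer Control arrays per treatment, which adds noise. The covariance was then 0.0162 against 0.0241. Replicate numbers did not pair the arrays: residuals of arrays with the same number had a median correlation of -0.0122, and the block removed degrees of freedom. Without dim genes 265 of 491 named genes and 100 of 116 list calls had a value. The brain covariate gave a value for 108 list calls, since the lists it is made of were excluded, the neuron covariate for 111, and the fit on the groups compared for 393 named genes. With an array left out its group kept 2 arrays. Array signal over background and 3 arrays per group limit the precision.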

Other observations

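The comparison of all 9 treated arrays with the 3 Control arrays, and all its tests, the counts over splits included, were chosen after the data were seen. It weighs the 3 treated groups equally. In limma 197 of 22180 genes were called, 52 higher and 145 lower, with 3441 at an unadjusted p under 0.05. The count was 1 without Control replicate 1, 5 without Control replicate 2, 838 without Control replicate 3, 240 without TMZ replicate 1 and between 58 and 114 without any other array; with the neuron score as a covariate it was 0. Of the called genes, 180 had treated and Control arrays that did not overlap; over all genes 941 did (4.24%), where chance gives 0.909%. Among 100 splits of the arrays into 9 and 3, the real one included and the others random, the real one alone gave as many genes (highest other 1). Because the grouping was chosen after Control was seen to stand apart, neither this count nor the split count and exact p values below exclude chance.

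Moxd1 was lower by the largest amount (-2.60 ± 0.28 SE, adjusted p = 0.00493), followed by Top2a (-1.58 ± 0.22, adjusted p = 0.0157) and Mlkl, which carries out necroptosis (-1.45 ± 0.27, adjusted p = 0.0328). Ifitm3 and Lgals1 were each at -1.39, Ect2 at -1.31, AI662270 at -1.26, Ccna2 at -1.21, the B cell chemokine gene Cxcl13 at -1.18 and Nxf3 at -1.17. The largest rises were in Zfp932 (0.73 ± 0.12, adjusted p = 0.023) and Atp13a5 (0.46 ± 0.05, adjusted p = 0.00493), then Krtap5-5 (0.42), Inca1 (0.38), Tfr2 (0.36), Kcnq1ot1 (0.35), Wsb1 (0.32), Cep70 (0.30), Minar2 (0.29) and Fam227a (0.29). Among microRNA genes, of which 483 were tested, 13 were called higher and 1 lower, the called ones counted with a slightly broader symbol match. Over all 22180 genes 52 were called higher and 145 lower.

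Camera called 19 of 34 lists in this comparison, 17 of them lower; with an estimated correlation it called 0 (lowest adjusted p 0.0886) and fry called 7. Calls lost on leaving out an array were those of checkpoint receptors (Control replicate 2 or Combination replicate 1), cytotoxic lymphocytes and alternatively activated macrophages (Control replicate 2), endothelium (Control replicate 3), neurons (Control replicate 1 or 2) and oligodendrocytes (Control replicate 1, TMZ replicate 3, Anti-PD-1 replicate 1 or Combination replicate 2). With the neuron score as a covariate 11 lists were called. Of 100 splits into 9 and 3 arrays, 4 gave 19 or more lists, the real one included (highest other 19). Scores of 4 lists separated the treated from the Control arrays at an exact p = 0.00455, the smallest that the 220 splits allow (two-sided, exact adjusted p = 0.0386 over 34 lists). These were mitosis (-0.76; 21 members called over all genes, 29 adjusted over the list alone), DNA replication (-0.36; 11 called, 20 adjusted over the list alone), natural killer cells (-0.11; 0 called in limma by either count, and not called by camera, adjusted p = 0.0601, or 0.199 with an estimated correlation) and inflammatory cytokines (-0.14; 0 called in limma by either count). The natural killer cell genes had the lowest mean level of the 34 lists, 3.84 log2, and share Gzma, Eomes and Prf1 with the cytotoxic list. Astrocyte markers had a mean of -0.01 where camera gave the direction as higher (adjusted p = 0.53).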
